A study of Caenorhabditis elegans with 2 samples.

How the data were processed

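Binding of an eGFP-tagged R02D3.7 protein was measured by ChIP-seq in whole L2 larvae of Caenorhabditis elegans. The labels give 1 group with 2 biological replicates, and each library was given its replicate number from its label. The strain, OP218, carries the unc-119(ed3) mutation and the integrated transgene wgIs218, from which the tagged protein is made. The annotation used here names the gene rcat-1.

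The deposited files are narrowPeak lists on the ce10 and ce11 builds, 8 in all. Each build has a list of 30000 candidate regions for each replicate, a list of 30000 candidate regions called on the reads of both replicates joined, and the set kept after the irreproducible discovery rate (IDR) step. The notes deposited beside the sample files state that the candidate lists were called against a control file, which was not analysed here. The peak caller, the aligner and their versions are not given in the sources used here. Column 7 of each deposited list holds a signal value per region, as the authors' peak caller gave it. The scale of this signal is not stated, and it is not divided by read depth, since it was higher in the joined list than in either replicate. Column 9 of each deposited list holds a score that is by format the −log10 of a q-value. It was slightly negative for some regions of the joined lists and tied at its highest value for 345 regions of the ce11 joined list, so it was not used for ranking. Read depth per library is unknown, and signal values were used only to describe and rank peaks within a list, or side by side with that limit stated.

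The ce11 lists are the main data. Coordinates are 1-based. Genes came from Ensembl release 115 on WBcel235, whose sequence is that of ce11, and sequence came from the RefSeq copy of the same assembly. No coordinates were converted between builds. A promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated 5′ end of a protein-coding gene (29784 5′ ends of 19973 genes). A gene was called bound when an IDR summit lay in its window. Candidate regions were matched to IDR peaks by overlap of at least 1 bp and the nearest summit.

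The share of summits in promoter windows and the overlap of the replicates' strongest peaks were compared with 100000 random placements within chromosomes (permutation tests, two-sided and one-sided). Chromosome shares were compared by two-sided exact binomial tests. Signal inside and outside promoter windows was compared by a two-sided permutation test with 100000 resamples over peaks. Alternatives used 10000 resamples for the overlap of replicates and for signal. Gene lists were tested by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 29 lists. Lists of protein-coding genes were set against all other protein-coding genes, and RNA classes against all other genes (46890 genes in all). Lists were defined by gene symbol, so that a few members have other functions than the list's name says, and these are named where they were bound, except for 1 item that is not reported here. For sequence, each of the 2080 6-mers (strands joined) was counted in the 101 bp around each summit and in windows of the same size centred 300 bp to each side. An exact sign test compared summit and flank on chromosomes I, III and V, and the 10 6-mers with the smallest p were then tested on II, IV and X. Shares carry 95% Wilson intervals, or exact Clopper-Pearson intervals for chromosome shares. The limit that a count of 0 allows is given as 3 counts over the total, which is tighter than the upper Wilson limit printed beside it. Intervals and limits cover counting error only. Peaks are not independent replicates, so all p-values describe this set of peaks and not the spread between animals.

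The tests, the gene lists, the windows and the alternatives were fixed before the data were examined, unless stated otherwise. The genes named are those at the 25 strongest IDR peaks with a gene in the window, the 4 strongest bound members of each list past the threshold, up to 2 of every other list, R02D3.7 and unc-119, and the genes at the 3 IDR peaks whose ranks within the set differ most between replicates. Genes named outside this rule, such as those at peaks outside promoter windows, were chosen after their values were seen. Alternatives tried were a stricter peak set, each replicate alone, other promoter windows, other assignments of peaks to genes, other backgrounds, other sequence windows and word lengths, other rules of overlap, and the ce10 lists.

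The procedures were tested on simulated data. In 50 simulated sets, bound genes were drawn independently of one another from all 46890 genes. A list with 50% of members bound was called in 100% of sets. Lists with 25%, 15% and 10% bound were called in 94%, 100% and 34% of sets, for lists of the size of the proteasome, collagen and replication lists. Unchanged lists were called in 0.32% of 1250 tests. Genes that share a peak were not simulated, so this rate does not cover lists whose members lie under shared peaks. A 6-mer placed in 15% of random windows was found in 100% of 10 runs over the 2080 6-mers. In those runs 20.7% of the 87 other leading 6-mers were also called, which fell to 1.56% of 64 once 6-mers sharing 4 bases with the placed one were left out, and with nothing placed 0 of 200 leading 6-mers were called. The sign test therefore also picks up shifted copies of a real word, and the 10 leading 6-mers are not 10 separate sequences. With 542 summits placed at random, 5% of 100 sets gave a promoter share with p under 0.05.

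Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.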

Results

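The data are peak lists from ChIP-seq of eGFP-tagged R02D3.7 (gene rcat-1) in whole L2 larvae, with 2 biological replicates in 1 group. The IDR set held 542 peaks on ce11 and 548 on ce10. The peaks had a median width of 330 bp (range 83 to 354) and signal values from 39.1 to 1699, with a median of 69.3. The IDR set was made up of exactly the 542 regions of highest signal among the 30000 candidates of the joined reads. Chromosomes I and III held 100 and 106 peaks, IV and V held 91 and 87, and X held 54, and chromosome II held 19.2% of the set. Read depth is unknown. Sorted signal values of the IDR sets of the builds differed by a median of 0.0056%.

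The first question was where the tagged protein lay relative to genes. The strongest peak (chromosome II, 4299262 to 4299605, signal 1699) lay between genes, with its summit 217 bp upstream of sco-1, which encodes a copper chaperone of cytochrome c oxidase. The next lay between rpl-20, encoding a large ribosomal subunit protein, and Y17G9B.5 (IV, 4749928 to 4750232, signal 1374), and that of rank 3 between frg-1 and ubq-2, which encodes a ubiquitin and ribosomal protein fusion (III, 12978828 to 12979166, signal 1199). The peak of rank 4 lay in an intron of M03C11.3, just upstream of hat-1 (signal 1148), and that of rank 5 at rbc-2, Y54F10AM.15 and ndua-8 (signal 1140). Other genes at the 25 strongest promoter peaks encode RNA processing proteins (exos-2, rbd-1, thoc-7), metabolic enzymes (hmgs-1, dld-1, gmps-1, cox-10) and chromatin proteins (htz-1, wapl-1), with signals from 441 to 943.

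Further genes at these 25 peaks were F25B4.4, T23F6.3, ska-3, rps-12, cic-1, strm-1, rpl-29, H35B03.2, rbg-3, rps-0, Y38E10A.33, abhd-11.2, nsph-1.2, R05D3.8, rfp-1, rpl-23, swp-1, F55A11.1, syx-5, acl-1, mrps-7, Y57G11C.3, Y39B6A.3, pph-5, cap-2 and F56A8.3, the last with a signal of 438. Of these, acl-1 alone lies on X.

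Of the 542 IDR summits, 454 (83.8%, Wilson interval 80.4 to 86.6) lay in the promoter window of a protein-coding gene. Random placement gave 26.4% (95% range 22.7 to 30.1), a 3.18-fold difference with a permutation p of 2e-05, the smallest the permutations can give. Outside promoter windows, 53 summits lay between genes (9.78%, against 23.9% at random), 31 in introns (5.72% against 27.9%), 2 in coding exons (0.369% against 19.2%) and 2 in 5′ UTRs. No summit lay in a 3′ UTR outside the windows, which allows a share of up to 0.554% at 3 counts (Wilson limit 0.704%). The median summit lay 168 bp upstream of the nearest 5′ end, 325 summits lay within 250 bp of one, and 46 lay over 2000 bp away. The share depends on the width of the window, at 5.49-fold over random with 500 bp upstream and 100 bp downstream and 2.06-fold with 2000 bp upstream.

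**Figure D1:**
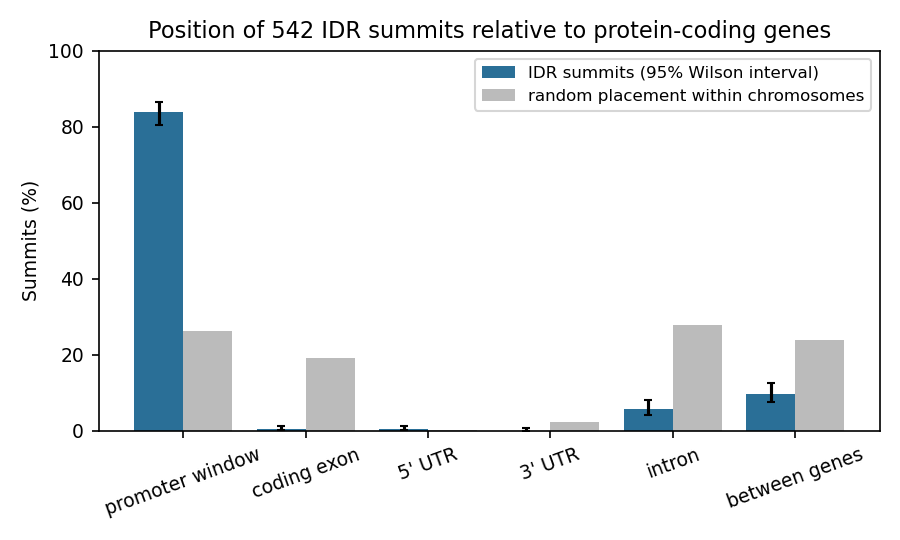
Share of the 542 IDR summits in each position class (percent, blue, with 95% Wilson intervals) beside random placement within chromosomes (grey). Promoter windows held 83.8% of summits against 26.3% expected. The grey values are the share of bases in each class, weighted by the number of peaks on each chromosome. Each summit was counted in 1 class, with promoter windows first.

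**Figure D2:**
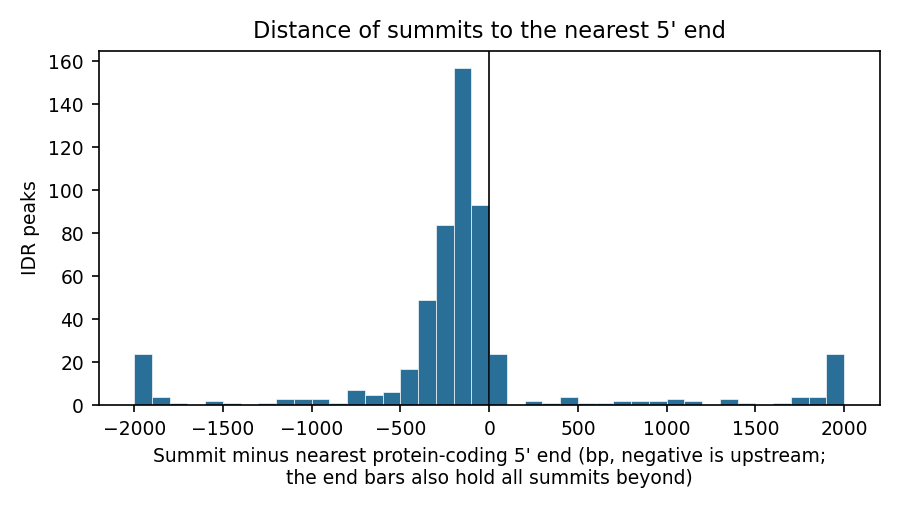
Number of IDR peaks by signed distance in bp from the summit to the nearest protein-coding 5′ end, in bars of 100 bp, with negative values upstream. The median lies at -168 bp, and the end bars also hold all summits beyond 2000 bp.

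Peaks in promoter windows had a median signal of 73.3 (quartiles 51.7 and 145, n = 454), against 54.4 (44.7 and 93.0, n = 88) for the others. The difference of 18.9 passed a permutation test over peaks (p = 0.0173). On X the medians went the other way, at 67.7 inside windows and 99.1 outside (30 of the 88), against 73.6 and 49.8 on autosomes, a contrast that was not tested. With a 2000 bp window the difference was 12.2 (permutation p = 0.101), and among peaks in the top 542 of both replicates, where 43 lay outside windows, it was 15.4 (p = 0.32). In the top 50% of IDR peaks, a set chosen by the signal itself, it was -11.8 (permutation p = 0.676). The strongest peaks with no promoter window lay near ztf-27 (II, summit 10388240, signal 392) and in an intron (I, summit 5261803, nearest 5′ end that of vep-1, signal 315).

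The next question was which genes were bound, a word that names the position of a summit only. Control reads were not used here, so whether the tagged protein itself or general accessibility of promoters gives the signal was not tested. IDR summits lay in the windows of 694 of 19973 protein-coding genes (3.47%), and 218 peaks had 1 such gene, 223 had 2 and 13 had more. Cytosolic ribosomal protein genes were bound most often, at 44 of 81 (54.3%, interval 43.5 to 64.7) against 3.27% of other genes, with signals of 1374 at rpl-20, 757 at rps-12, 592 at rpl-29 and 587 at rps-0. Genes of the mitochondrial respiratory chain followed, at 14 of 40, led by cox-10 (582), cox-5A (205), nuo-6 (174) and atp-1 (81.8). Translation factors were bound at 10 of 41, with eef-1A.1 (165), eif-2gamma (148), ifg-1 (143) and eif-3.C (127). Chaperones were bound at 13 of 60, with the chaperonin subunits cct-8 (260) and cct-1 (188), hsp-90 (177) and dnj-9 (155).

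Splicing factors were bound at 7 of 36, with sftb-6 (366), rsp-2 and rsp-1 (107, at 1 shared peak) and snr-4 (52.5). Proteasome genes were bound at 6 of 33, with rpn-3 (99.9), rpn-8 (96.5), rpn-12 (67.6) and rpn-11 (58.2). Mitochondrial ribosomal protein genes were bound at 9 of 70, with mrps-7 (465), mrpl-40 (393), mrps-25 (266) and mrpl-49 (185). Replication and cell cycle genes were bound at 6 of 58, with pcn-1 (108) and cdc-6 (68.7), and also cdc-48.1 (308), known for its role in protein degradation, and cdk-5 (88.96), known for its role in neurons. Genes of small nuclear and nucleolar RNAs were bound at 46 of 475 (9.68%) against 1.83% of all other genes. The highest signals in this class were 757 at F54E7.11 and F54E7.10, under the peak shared with rps-12, and 389 at K11H12.13 and K11H12.12, under that shared with rpl-15. The annotation also puts mir-1831 in this class, whose symbol is that of a miRNA gene, and it was counted among the 46, at a peak of signal 57.4.

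The odds ratios of these lists were 35.2 for cytosolic ribosomal proteins (95% interval 22.03 to 56.4), 15.2 for the respiratory chain (7.32 to 30.4), 9.08 for translation factors (3.95 to 19.1), 7.81 for chaperones (3.86 to 14.8), 6.76 for splicing factors, 6.22 for the proteasome, 5.76 for the RNA genes (4.12 to 7.89), 4.14 for mitochondrial ribosomal proteins and 3.22 for replication and cell cycle. Adjusted p by Fisher's exact test ran from 2.28e-41 for cytosolic ribosomal proteins to 0.0312 for replication and cell cycle. Across settings the odds ratio ran from 18.1 to 37.5 for cytosolic ribosomal proteins, 9.28 to 16.9 for the respiratory chain, 8.43 to 14.9 for translation factors, 3.12 to 10.6 for chaperones and 3.36 to 9.98 for the proteasome. The RNA genes were set against all other genes, so their odds ratio is not on the scale of the protein-coding lists. Against genes other than piRNA genes, a setting chosen afterwards, it was 3.96, with 2.63% of the others bound. That was the lowest value for the RNA genes across settings, which ran up to 7.73. With 1 gene per summit 26 of 81 cytosolic ribosomal protein genes (32.1%) were bound, at an odds ratio of 21.8. The replication and cell cycle list lost its call under 6 of the 8 settings that could change it, with an adjusted p of up to 0.201. Chaperones and mitochondrial ribosomal proteins lost theirs when each summit was given 1 gene (adjusted p = 0.095 and 0.0543 by Fisher's exact test), and splicing factors and the proteasome in the top 50% of peaks (0.0842 and 0.249).

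Large gene families of sensory, defence and regulatory function were bound less often than other genes. Chemoreceptors were bound at 2 of 1364 (0.147%, odds ratio 0.038, adjusted p = 5.67e-18 by Fisher's exact test). The bound members include srh-16, with a signal of 149. No gene of the detoxification list was bound (0 of 215, which allows a share of up to 1.4% at 3 counts, with a Wilson limit of 1.76%). F-box genes were bound at 2 of 322 (fbxb-85 with a signal of 104.1, fbxa-90 with 52.5), C-type lectins at 1 of 240 (clec-53, 47.7), nuclear hormone receptors at 2 of 270 (nhr-47, 60.3, and nhr-142, 41.1), and homeobox and other developmental factors at 1 of 187 (ceh-38, 90.1). Adjusted p by Fisher's exact test were 0.00295, 0.00469, 0.00919, 0.0154 and 0.0464 for the last 5 lists. The odds ratio of the chemoreceptors ran from 0.0297 to 0.0712 across settings. The call was lost under 6 of the 8 settings that could change it for the developmental factors (adjusted p up to 0.656), under 5 for nuclear hormone receptors (up to 0.246) and in the top 50% of peaks for detoxification, F-box and lectin genes (0.0842, 0.0842 and 0.052).

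The other lists did not pass the test, including the markers of single tissues. Muscle and intestine genes had no bound member (0 of 49 and 0 of 60, which allow up to 6.12% and 5% at 3 counts, with Wilson limits of 7.27% and 6.02%). Epidermis and moulting had 1 of 93, and that 1 is nasp-2 (43.2), taken by the symbol rule only. Synaptic genes had 2 of 37 (ric-19, 291, and unc-57, 39.6), neuropeptides 1 of 140 (ins-39, 107), germline genes 4 of 54 (nos-3, 189, and puf-9, 120), sperm genes 1 of 72 (spe-39, 66.4) and histones 1 of 72 (his-37, 125). Collagens had 4 of 173 (col-8, 214, and col-71, 46.2), the vacuolar ATPase 1 of 20 (vha-1, 42.1), tRNA genes 12 of 612 (ZK994.t2, 82.3, and Y38E10A.t1, 66.1) and miRNA genes 3 of 261 (cel-mir-2213, 166, and cel-mir-5549, 165). Dosage compensation genes had 0 of 10 and heterochronic genes 0 of 13, lists too short to show a lower share. The heterochronic list was tested on its protein-coding members alone, without its miRNA members. The miRNA list turned higher when each summit was given the nearest 5′ end at any distance (odds ratio 3.13, adjusted p = 0.000325 by Fisher's exact test), and neuropeptides passed as lower with the 500 bp window (adjusted p = 0.0487).

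**Figure D3:**
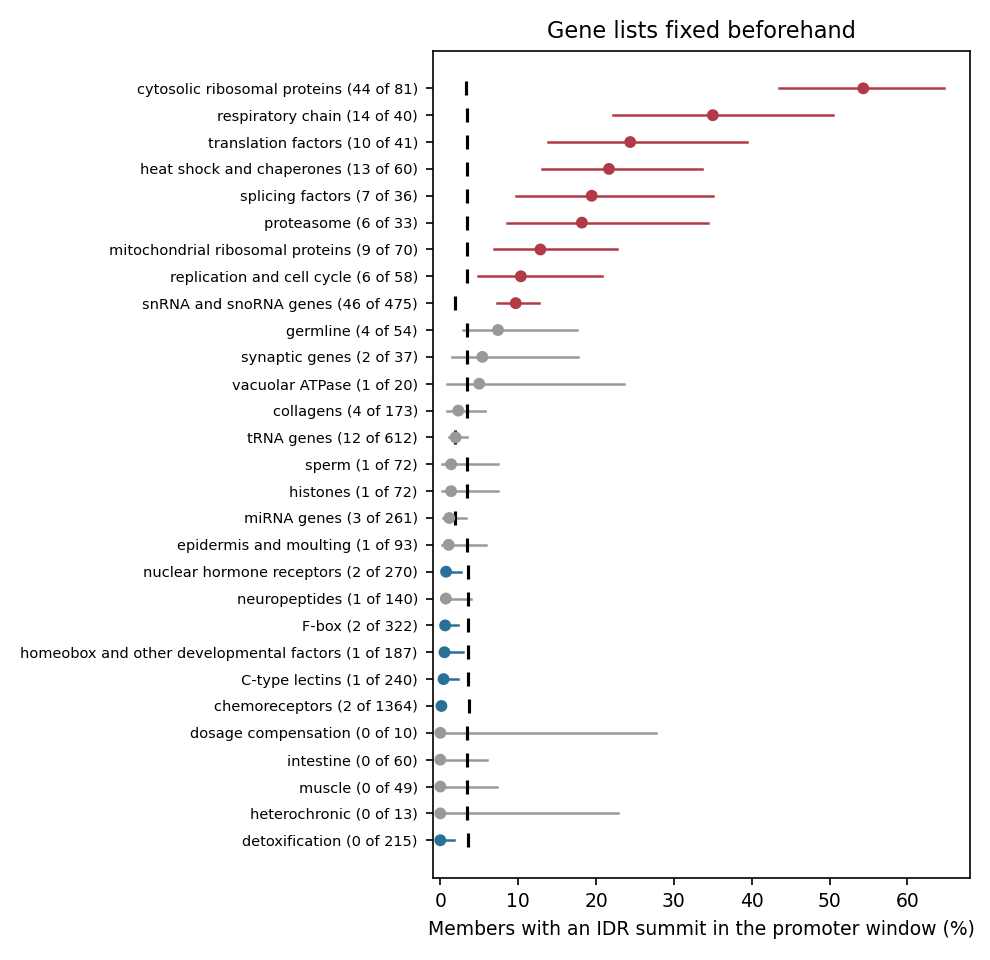
Members of each gene list with an IDR summit in the promoter window (percent, points, with 95% Wilson intervals) and the share of other genes of the same kind (black ticks). Red lists were bound more often and blue lists less often at an adjusted p under 0.05, from 54.3% of cytosolic ribosomal proteins to 0 of 215 detoxification genes, and grey lists did not pass.

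Across chromosomes, X carried 54 peaks (9.96%, exact interval 7.57 to 12.8), below its 13.7% of protein-coding genes. The ratio was 0.729 by a two-sided exact binomial test (p = 0.0103). Chromosome III had the most peaks per gene (40.2 per 1000 protein-coding genes) and V the fewest (17.4), with X at 19.8. The lower share of all peaks on X was seen in replicate 1 alone and not in replicate 2 alone. The top 542 peaks of replicate 2 alone gave 15.3% on X and a ratio of 1.12 (exact binomial p = 0.261). The lower share also missed the threshold in the top 50% of peaks (ratio 0.81, exact p = 0.25). Outside promoter windows lay 52 of the 83 X peaks of replicate 2 (62.7%) and 29 of the 52 of replicate 1 (55.8%). The share of all peaks therefore does not describe promoter peaks, of which 24 of 454 lay on X, a share that was not tested. Autosomal arms, taken as the outer parts of each autosome when it is cut in 3 by length, held 305 of 488 autosomal peaks (62.5%, exact interval 58.0 to 66.8) against 61.9% of genes, a difference that did not pass the exact binomial test (p = 0.816).

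The replicates were compared next. Each IDR peak overlapped a candidate region of replicate 1, and 528 of 542 (97.4%) also one of replicate 2. Both replicates gave the peaks at sco-1, rpl-20 and ubq-2 ranks 1, 2 and 3. Of the top 542 peaks of replicate 1, 333 (61.4%, Wilson interval 57.3 to 65.4) overlapped a top 542 peak of replicate 2, against a mean of 0.34% by chance (permutation p = 1e-05, the smallest the permutations can give). The shared share fell with the length of the lists, from 80.4% for the top 271 to 39.8% for the top 1084. Signal values across the 528 peaks correlated with a Spearman rho of 0.756 and a Pearson r of 0.855 on log2 values. This is across peaks, which are not independent replicates, and which were chosen for high joined signal. Over the 8693 other candidate regions of the joined list found in both replicates, rho was 0.0717. Within bins of joined rank, rho was 0.882 for ranks 1 to 100 and 0.228 for 101 to 200. In the 3 later bins it was -0.349, -0.508 and -0.625. Cutting a list by the joined signal can itself lower rho, so neither these values nor the 0.0717 measure agreement alone.

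The lower part of the IDR set rested mostly on replicate 1. Median signal at the IDR peaks was 54.6 in replicate 1 and 20.1 in replicate 2, on scales that are not known to be comparable. All 100 strongest IDR peaks were in the top 542 of both replicates, as were 98 of the next 100, but only 12 of the last 142 (8.45%). Of these 142, 95 were in the top 542 of replicate 1 and 42 in that of replicate 2. By ranks counted within the IDR set, the peaks that differed most lay at C49A9.10 (signal 101 in replicate 1 and 8.20 in replicate 2), H41C03.3 (67.8 and 5.57) and between nduf-6 and nars-1 (15.2 and 24.5).

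**Figure D4:**
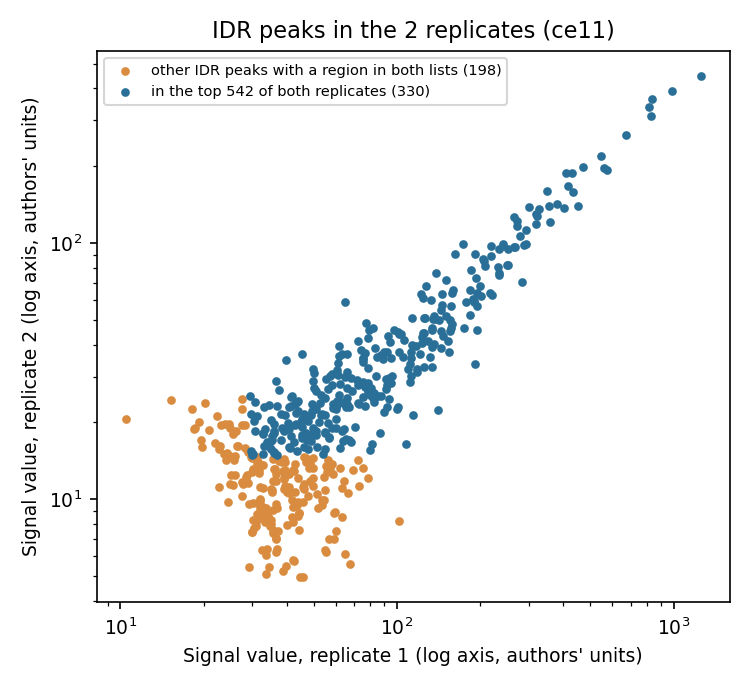
Signal value of the 528 IDR peaks with a region in both replicate lists, replicate 1 on the x axis and replicate 2 on the y axis, both log axes in the authors' units. The 330 peaks in the top 542 of both replicates (blue) extend to the highest signals, and the other 198 (orange) lie at low signal in 1 or both replicates.

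Words of 6 bases were then compared between summits and their flanks. On chromosomes I, III and V (293 peaks), 156 of 2080 6-mers were more frequent and 82 less frequent in the 101 bp around the summit. The word ACGCGC occurred in 20.1% of summit windows against 0.341% of flanks, GACGCA in 17.1% against 0.341%, and CGTAAA in 29.01% against 4.78%. On the held-out chromosomes II, IV and X (249 peaks), these shares were 18.5% against 0.803%, 18.1% against 1.61% and 26.9% against 3.61%. All 10 leading 6-mers passed there by the exact sign test, with adjusted p from 1.04e-13 to 6.16e-06. At least 1 of the 10 lay in 71.9% of the held-out summit windows and 12.4% of their flanks. The leading words depended on the peaks used. Only 3 of these 10 were among the 10 leading words in the top 50% of peaks, 4 with replicate 2 alone and 7 with replicate 1 alone. Summit windows had more GC than flanks (45.8% ± 7.78 against 36.1% ± 5.89, mean ± SD over windows), so the flanks did not match the summits in base composition. With words of 8 bases the leading one was CGTAAATC, in 22.5% of summit windows on I, III and V and in 18.9% on II, IV and X.

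The tagged gene lies on chromosome IV (253619 to 255429, minus strand), and no candidate region in the joined list or in either replicate's list overlapped it. The nearest IDR peak (IV, 240340 to 240669, rank 96, signal 180) lay 12.95 kb away, with its summit in the 5′ UTR of cogc-8 and in the windows of cogc-8 and fnta-1. No IDR peak lay within 20 kb of unc-119 (III, 10902641 to 10908935), whose strongest overlapping candidate in the joined list ranked 3289 with a signal of 21.6.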

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

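The restriction to peaks in the top 542 of both replicates and the test of RNA lists against genes other than piRNA genes were chosen after the data were seen. The top of the joined list was the IDR set itself, and leaving out piRNA genes cannot change protein-coding lists, so these are not counted below. Of 48 other alternatives of the main results, 40 kept their side of the threshold or a like value, among them each alternative of the promoter share, the replicate overlap and, by its count of words that passed, the summit sequence. The words themselves changed, with 3 to 7 of the 10 leading 6-mers shared with the other sets and windows of 6-mers. Some of the 48 were close to the main setting from the start, so their agreement adds little. In replicate 1, 493 of the 542 IDR peaks matched a region of its top 542, and the ce10 lists came from the same reads. The arm share stayed short of the threshold in each, at ratios from 0.938 to 1.01 that fall on both sides of 1. Leaving out 1 replicate gave a promoter share of 2.58 to 3.19-fold, an X ratio of 0.702 to 1.12 and a signal difference of 8.50 to 16.3. The X ratio was 0.81 in the top 50% of peaks and 0.776 in the peaks high in both replicates, and neither passed, with 271 and 330 peaks in place of 542. The signal difference was -11.8 in the top 50%, a set chosen by signal and so no test of this result, though counted among the 48, 15.4 in the peaks high in both with 43 outside windows in place of 88, and 12.2 with the 2000 bp window. The number of gene lists past the threshold was 8 in place of 15 in the top 50% of peaks, where fewer peaks were tested, and 10 to 15 elsewhere. The correlation of replicates was 0.875 in the peaks high in both. Of the alternatives of single lists, 209 were the same, 24 lost and 1 gained a call, and 1 turned, the miRNA list at an odds ratio of 3.13 with the nearest 5′ end at any distance. The cause was not tested for the X ratio, the signal difference or the miRNA list. A stricter IDR threshold was not run, because the score it needs is 0 for each peak. No paired analysis was possible because there is 1 group. Unknown depth limits any comparison of signal between replicates.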

Other observations

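The counts of shared windows, the SL2 genes, the peaks by replicate on X, the X peaks without GCGCAGGG, the words left without CGTAAATC and both tests of shared windows at RNA genes are tests chosen after the results were seen. The tests of X peaks by window, of GCGCAGGG, of a repeat and of matched promoter windows were not in the original plan either. They followed patterns already seen, with predictions written before they were run. The counts of CGTAAATC by rank were also chosen afterwards. Many summits lay in the windows of more than 1 gene, without showing which gene they belong to. Of the 454 summits in promoter windows, 236 (51.98%, Wilson interval 47.4 to 56.5) lay in the windows of 2 or more protein-coding genes, against 11.1% of 18160 random positions in windows (exact binomial p = 3.73e-102). Summits lay mostly between genes and close to a 5′ end, which random positions in windows need not. The p-value therefore does not show a preference for shared windows as such. Among genes of the spliced leader SL2, which is joined to downstream genes of operons, 4 of 18 were bound, with signals of 250 at sls-2.4, 188 at sls-2.1, 168 at sls-2.2 and 73.9 at sls-2.8. The summit at sls-2.2 lay in no protein-coding window. The word CGTAAATC was present at 57% of the 100 strongest peaks and 7.75% of the last 142, and median signal was 174 in the windows with it and 62.8 in those without.

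IDR peaks on X lay outside promoter windows more often than autosomal ones, at 30 of 54 (55.6%) against 58 of 488 (11.9%), an odds ratio of 9.27 (95% interval 4.84 to 17.7, Fisher's exact p = 1.39e-12). A lower density of windows on X gives only 1.31 by uniform random placement, and each replicate's own top peaks gave the pattern, with 9.77 and 4.53. Uniform placement does not account for a set that lies mostly at promoters. The odds ratio also does not separate few promoter peaks on X from many peaks outside windows. X holds 17.7% of chromosome length, with 24 peaks inside windows against 430 on autosomes, and 30 against 58 outside. By these counts X was low inside windows and high outside relative to its length, and neither was tested. The word GCGCAGGG, part of a motif known from X sites that recruit the dosage compensation complex, lay within 100 bp of 10 of the 30 X summits outside windows (33.3%, interval 19.2 to 51.2). It lay at 1 of 58 such autosomal summits (odds ratio 28.5, Fisher's exact p = 5.62e-05) and 0.12% of random X positions, and inside windows at 3 of 24 X and 0 of 430 autosomal summits, so it is not particular to X peaks outside windows, and without the peaks that carry it the odds ratio was still 7.18. As a hypothesis, part of the X peaks, inside and outside promoters, may lie at such sites, which leaves most X peaks outside promoters unexplained; whether the tagged protein itself or the general accessibility of these sites gives the signal was not tested, and neither control reads nor coordinates of such sites were used here.

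Leading 6-mers were far more frequent at promoter summits than in flanks, and base composition with position relative to the 5′ end is a candidate explanation. Windows of unbound genes at the same offset and within 2 points of GC carried 1 of the 10 in 24.3%. The share was 77.0% at 196 promoter summits on II, IV and X, a ratio of 3.17 (95% interval 2.75 to 3.67). This argues against GC content and offset as the whole cause. Pairs of bases were not matched, though each of the 10 words holds CG, nor was the kind of gene. Composition beyond GC content and the class of promoter therefore remain open. For the summits with CGTAAATC, copies of a dispersed repeat cannot be told apart from a bound site. The word was 2.02 times as frequent in the genome as a Markov model of its bases gives, between the bounds set in advance. Of its windows, 31.9% were soft-masked over most of their bases, against 10.7% of the others. Of all genomic bases, 35.7% were soft-masked, another measure that does not give the share of such windows in the genome. In the 429 windows without CGTAAATC, ACGCGC still lay in 20.3% against 0.233% of flanks, so a repeat with CGTAAATC leaves the GC-rich words to be explained. No biological explanation was tested.

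Small nuclear and nucleolar RNA genes were bound more often than other genes, and windows shared with protein-coding genes are a candidate source. Summits outside protein-coding windows still reached 15 of the 46 genes. Among non-coding genes with window bases outside protein-coding windows, piRNA genes left out, such summits reached 15 of 437 against 39 of 10739 others. The odds ratio was 9.75 (95% interval 4.95 to 18.3, Fisher's exact p = 1.28e-09). These others are a mixed class, with 27 of 7511 genes annotated as ncRNA, 9 of 592 tRNA genes and 2 of 2091 pseudogenes reached. The odds ratio therefore depends on the comparison class, and none was computed against tRNA genes alone. Relative to this mixed class, the value argues against sharing as the whole cause. For the other 31 of the 46 genes, binding to the RNA gene and to the coding neighbour cannot be told apart. No summit lies in their windows alone. No biological explanation was tested.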
